A study of Mus musculus with 18 samples.

How the data were processed

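The series holds 18 samples of mouse embryonic fibroblasts, and 8 of them had a processed file used here, 1 peak list for each of 4 histone marks in each of 2 conditions. The other 10 samples (RNA, Rb immunoprecipitation and input libraries) were not analysed here. Groups were taken from the sample labels, with 1 library per mark and condition. Per the labels, the antibodies were against pan-acetyl H3, H3K4me3, H3K9me3 and H3K27me3. The labels number all 8 immunoprecipitated libraries replicate 3 and the Cre input replicate 3, but the GFP histone input replicate 1. Which input served as control for which list is not given in the sources used here.

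Per the submitters' processing notes, the tools were BWA, SAMtools 0.1.18, bedtools 2.16.2 and MACS 1.4.1 (a peak caller), besides TopHat2 2.0.3, Bowtie2 2.0.0.6, Cufflinks 2.0.1 and Cuffdiff, and the genome build was NCBIM37. The notes do not say which tool was used for which sample. Peak names in the lists begin with the name of MACS. Peaks were called per library, since each list belongs to 1 sample. The lists give chromosome, start, end, a peak name and a score. The deposited score has no header and no unit. Its lowest value was 50 to 50.02 in every list and its highest 3233 in 6 of the 8. The duplicate handling, the minimum mapping quality and the background model were not given in the sources used here. Scores depend on sequencing depth and on the control library, so that they were used to rank and filter peaks within a list. Across lists, ranks were compared only over regions with a peak in both. The read depth of the libraries was unknown from these lists, and a longer list can come from more reads or a cleaner immunoprecipitation as well as from more marked regions.

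Peaks of the GFP and Cre libraries were compared by overlap of at least 1 base. A peak with no overlapping peak in the other library is called GFP-only or Cre-only, which means that the other list held no peak past the authors' threshold there. The chance level of overlap came from 100 circular shifts of the second list along each chromosome, with a fixed seed and the last peak end over all lists as chromosome length. Shares carry exact (Clopper-Pearson) 95% intervals, and ratios of counts carry the interval of the matching binomial share. Peaks were counted per chromosome as a share of the list, autosomes without chromosome X. Marks were set against each other within a condition by the same overlap. Regions with H3K4me3 and H3Ac in 1 library only were H3K4me3 peaks with no counterpart that overlapped an H3Ac peak with no counterpart. The overlap code was tested on simulated data, 12 thinned and jittered copies of the GFP lists, in which the share recovered differed from the true one by at most 0.954 percentage points. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9.

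The comparisons of peak numbers, sharing, chromosomes and marks, and the rule for regions named in the text, were fixed before the data were examined. The comparison of regions with H3K4me3 and H3Ac in 1 library only was chosen after the data were seen. The rule takes the 5 highest-scoring peaks found in 1 library only and the 5 widest peaks, per mark and library, and the text names the leading ones. The doubly marked regions on chromosomes 10, 11, 12 and 17 that are named besides these, the windows of chromosome X and the windows of chromosomes 1, 4 and 5 were chosen after their values were seen. Planned comparisons of promoters, bivalent promoters and 18 gene lists were not run, because the gene tables at hand are on assembly GRCm38.p6 and coordinates were not converted between builds. In place of promoters, H3K4me3 peaks were used. Alternatives were a minimum score of 100, peaks merged within 1000 bases, overlap of at least 50% of the peak, equal numbers of top-scoring peaks, and leaving out chromosome X.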

Results

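The study used mouse embryonic fibroblasts that carry a conditional allele of the retinoblastoma gene Rb, a tumour suppressor that holds back the cell cycle. The fibroblasts were infected with an adenovirus that delivers the Cre recombinase, which deletes the allele, or with an adenovirus that delivers green fluorescent protein (GFP), which leaves it intact. Cells for the histone experiments were expanded for at most 3 passages. Chromatin immunoprecipitation followed by sequencing was carried out for 4 histone marks: pan-acetylated histone H3 (H3Ac) and H3K4me3, which are found at active promoters, H3K27me3, which is laid down by Polycomb complexes at silent genes, and H3K9me3, which is found in heterochromatin. The question taken up here was how the histone peak lists of Cre and GFP cells differ. The series also holds RNA and Rb immunoprecipitation libraries, some of them labelled "with 4F", which were not analysed here. Each mark was represented by 1 library per condition, so that no difference between Cre and GFP cells had a replicate check and no p-value was computed. The 8 peak lists held between 3985 and 48778 peaks. The number of reads behind them was unknown. Intervals are exact 95% binomial intervals for shares and for ratios of counts, and 95% log-normal intervals for ratios of shares. They cover counting error only and treat peaks as independent, which neighbouring peaks are not. Positions are given in build NCBIM37, counted from 1, and no gene name was attached to a peak, because no annotation of that build was used here. Peak scores are the authors' own.

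The first question was whether marks of active promoters appeared or disappeared in Rb-deleted cells. Regions where an H3K4me3 and an H3Ac peak overlapped in 1 library, neither with a counterpart in the other, were more numerous in the Cre library. There were 411 H3K4me3 peaks without a GFP counterpart that overlapped an H3Ac peak also without one, against 74 such regions in the GFP library, a ratio of 5.55 (4.33 to 7.21). Score deciles alone, with the marks lost independently, gave 240 expected regions in Cre and 30.4 in GFP cells. Observed over expected had a Cre to GFP ratio of 0.703 (0.548 to 0.913). The expected numbers came from the same lists, so that a real gain of marks would raise them too. The excess may come from depth or threshold, and a real gain is not excluded. The strongest of the 411 lay on chromosome 12 from 27138900 to 27141725, on chromosome 16 from 97678800 to 97684969 and on chromosome 18 from 60534854 to 60539022. Each had an H3K4me3 score of 3100 in the Cre library and an overlapping Cre H3Ac peak, with scores of 812.1, 1461 and 1405. None of the 3 regions overlapped a GFP peak of any of the 4 marks. Most of the 411 were weak: their median H3K4me3 score was 105.8, against 886.9 for the whole Cre list, 195 scored below 100, and 17 lay above the median of the list.

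The 2 other H3K4me3 peaks among the 5 highest-scoring Cre-only ones carried H3Ac in both libraries. On chromosome 18 from 60371063 to 60375306 the H3K4me3 score was 3100, and the overlapping H3Ac peaks scored 3100 in the Cre list and 180.1 in the GFP list. On chromosome 5 from 7960114 to 7963534 the H3K4me3 score was 2772 in the Cre list. Further Cre-only regions with both marks lay on chromosome 11 from 48874307 to 48878000, with an H3K4me3 score of 1462, on chromosome 12 from 104679573 to 104682303, with 1451, and on chromosome 10 from 97027991 to 97030642, with 1374. These 3 regions follow the others in the ranking of doubly marked regions by H3K4me3 score. The region on chromosome 10 also held the second of the 5 highest-scoring Cre-only H3Ac peaks, with a score of 1434.

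Cre-only H3K4me3 peaks overlapped a Cre-only H3Ac peak in 14.4% of cases (13.1 to 15.7), and a GFP-only H3Ac peak in 2.66%. GFP-only H3K4me3 peaks overlapped a GFP-only H3Ac peak in 2.89% of cases (2.28 to 3.62), and a Cre-only H3Ac peak in 1.06%. Fewer GFP-only peaks carried H3Ac at all. Any H3Ac peak of the same library overlapped 516 of the 2559 GFP-only and 1472 of the 2859 Cre-only H3K4me3 peaks, which accounts for part of the contrast. Of the 2559 GFP-only H3K4me3 peaks, 657 overlapped the GFP H3K9me3 list and 274 the shorter Cre H3K9me3 list. Of the 2859 Cre-only peaks, 124 and 157 overlapped these lists. The highest-scoring GFP-only H3K4me3 peak spanned 9149 bases on chromosome 12 from 20231919 to 20241067, with a score of 1406 and no H3Ac. It overlapped a GFP H3K27me3 peak with a score of 237.9 and a Cre H3K9me3 peak with a score of 91.02. That Cre H3K9me3 peak, from 20231963 to 20254375, also overlapped a Cre H3K4me3 peak with a score of 916.6, outside the GFP-only peak. The second GFP-only H3K4me3 peak by score, on chromosome 2 from 155804764 to 155807215, had a score of 1155 and overlapped H3Ac in both libraries. With equal numbers of top-scoring peaks, 588 doubly marked regions were found in the Cre library only and 41 in the GFP library only. That setting shortens only the GFP lists, so that it can only widen the gap.

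**Figure D1:**
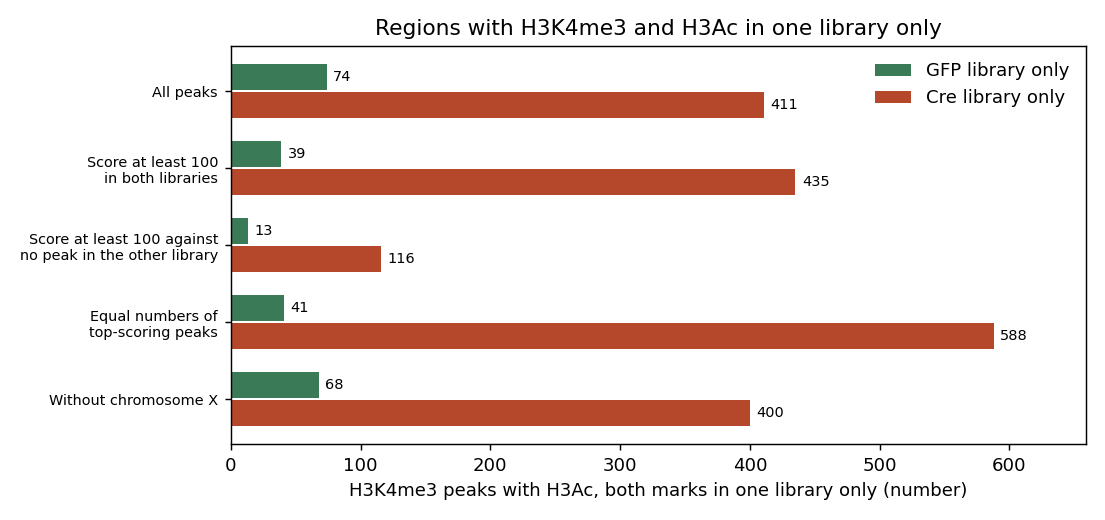
Horizontal bars give the number of H3K4me3 peaks that overlapped an H3Ac peak where neither peak had a counterpart in the other library, for the GFP and the Cre library and for 5 ways of choosing peaks. The Cre bar is longer in each pair, from 116 against 13 regions for peaks with a score of at least 100 and no peak in the other library to 588 against 41 for equal numbers of top-scoring peaks.

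Most H3K4me3 and H3Ac peaks were present in both conditions. For H3K4me3, 89.3% of the 23808 GFP peaks (88.9 to 89.6) and 87.4% of the 22621 Cre peaks (86.9 to 87.8) overlapped a peak of the other library, where shifted positions gave 2.98% and 3.08%. The Cre H3K4me3 peaks were wider, with a median of 1606 bases against 1375.5, and covered 43.4 Mb against 40.3 Mb. At a score of at least 100 the Cre list held 19452 H3K4me3 peaks and the GFP list 19353, a ratio of 1.01 (0.985 to 1.03). The lists were then of like length within counting error, but a score of 100 need not be an equal threshold in both. Scores depend on depth and control, and the median H3K4me3 score was 886.9 in the Cre and 564.7 in the GFP list. For H3Ac, the Cre list was shorter, with 42660 peaks against 48778, a ratio of 0.875 (0.863 to 0.886), and covered 75.9 Mb against 89.6 Mb. In the Cre library 84.6% of H3Ac peaks overlapped a GFP peak, and 73.4% of the GFP peaks overlapped a Cre peak.

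GFP-only H3Ac peaks were 12984 in number and Cre-only ones 6588. The highest-scoring GFP-only H3Ac peaks lay outside H3K4me3. They were on chromosome 12 from 16920750 to 16929367, with a score of 1902, on chromosome 2 from 117569272 to 117575903, with 1379, and on chromosome 3 from 141992128 to 141996745, with 1104, and none of them overlapped a peak of another mark in either library. By contrast, each of the 5 highest-scoring Cre-only H3Ac peaks overlapped a Cre H3K4me3 peak. The widest H3Ac peak of the GFP list spanned 54517 bases on chromosome 15 from 77617378 to 77671894, and Cre peaks covered 89.3% of it.

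**Figure D2:**
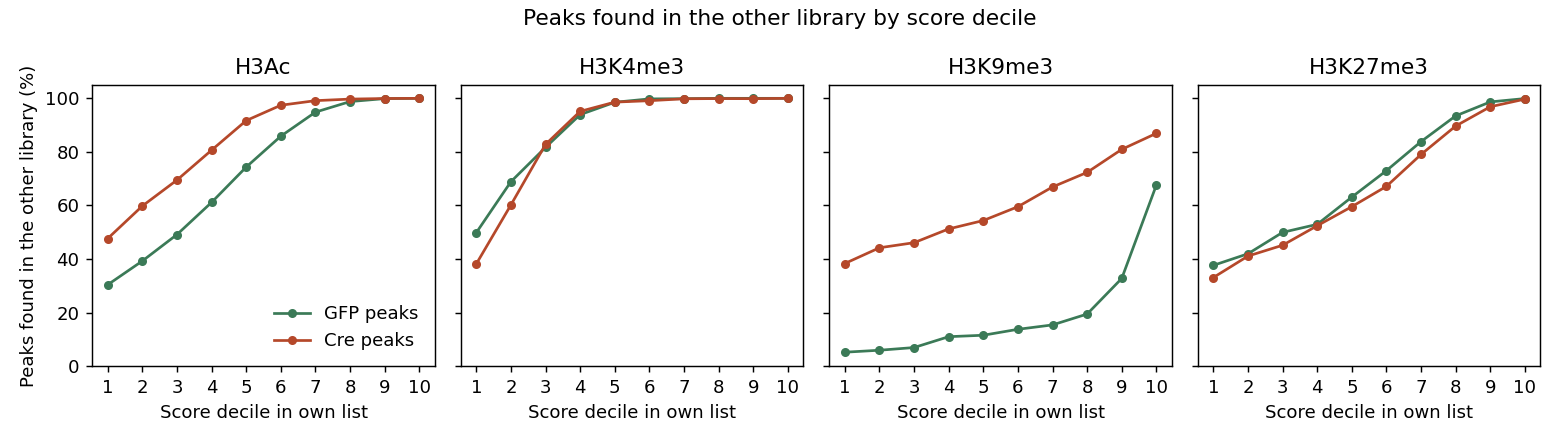
Points give the percent of GFP peaks found in the Cre library and of Cre peaks found in the GFP library, by decile of peak score within each list, with 1 panel per mark. In the top decile every H3Ac and H3K4me3 peak was found again, while 67.6% of GFP and 86.9% of Cre H3K9me3 peaks were.

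The next question was how the Polycomb mark H3K27me3 was distributed. On chromosome X, the Cre library held 7029 H3K27me3 peaks and the GFP library 1967. These covered 11.3 Mb and 2.53 Mb. The X chromosome took 19.3% of all H3K27me3 peaks in the Cre library and 5.45% in the GFP library, a ratio of 3.54 (3.38 to 3.72). Over all chromosomes the lists held 36381 and 36059 peaks. Outside chromosome X the Cre library held fewer H3K27me3 peaks, 29352 against 34092, and a smaller covered length, 61.1 Mb against 66.2 Mb. Among the 19 autosomes the ratio of the share of peaks, taken without chromosome X, ranged from 0.924 on chromosome 7 to 1.06 on chromosome 6.

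The additional H3K27me3 peaks on chromosome X were spread along it. Cre peaks covered more bases than GFP peaks in 28 of the 29 windows of 5 Mb that held any H3K27me3 peak, with a median ratio of 5.07 where the GFP library had peaks. Both libraries covered the most between 95 and 100 Mb, 1866 kb in Cre and 666.2 kb in GFP cells. The exception, from 60 to 65 Mb, held 0.939 kb in Cre and 1.90 kb in GFP cells. Nearly all GFP peaks on chromosome X, 90.5% (89.1 to 91.8), overlapped a Cre peak, and 20.9% of the Cre peaks (20.0 to 21.9) overlapped a GFP peak. On the other chromosomes those shares were 68.3% and 77.3%. Of the 5 highest-scoring Cre-only H3K27me3 peaks, 4 lay on chromosome X. The first spanned 8823 bases from 48134207 to 48143029, with a score of 1378, and the second 7591 bases from 91499542 to 91507132, with a score of 1104. The fifth lay on chromosome 11 from 111416622 to 111423192, with a score of 937.8.

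**Figure D3:**
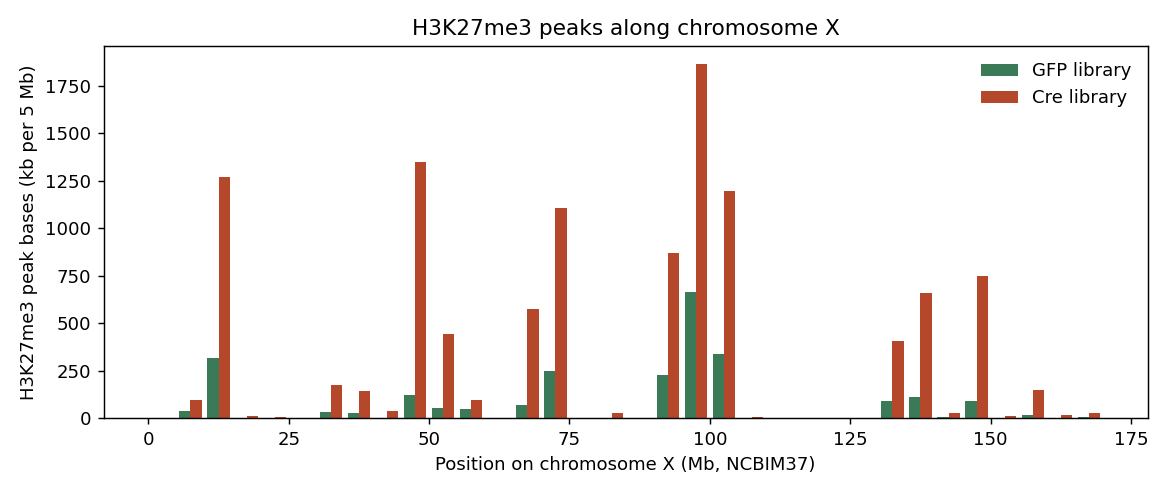
Bars give the bases covered by H3K27me3 peaks in the GFP and the Cre library, in kb per window of 5 Mb along chromosome X in build NCBIM37. Cre bars are higher in 28 of the 29 windows with a peak, and both libraries peak between 95 and 100 Mb.

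The other marks did not share this distribution. The Cre to GFP ratio of the share of peaks on chromosome X was 1.09 (0.991 to 1.21) for H3Ac, 0.955 (0.864 to 1.06) for H3K4me3 and 0.687 (0.599 to 0.788) for H3K9me3. On chromosome X the share of H3Ac peaks that overlapped H3K27me3 was 19.7% in the Cre library (16.9 to 22.7) and 3.16% in the GFP library (2.06 to 4.63). Of the 596 chromosome X regions with H3K4me3 in both libraries, 45 carried H3K27me3 in both, 103 in the Cre library only and 3 in the GFP library only. No chance level was computed for these overlaps on chromosome X, where H3K27me3 peaks covered 11.3 Mb in Cre and 2.53 Mb in GFP cells.

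**Figure D4:**
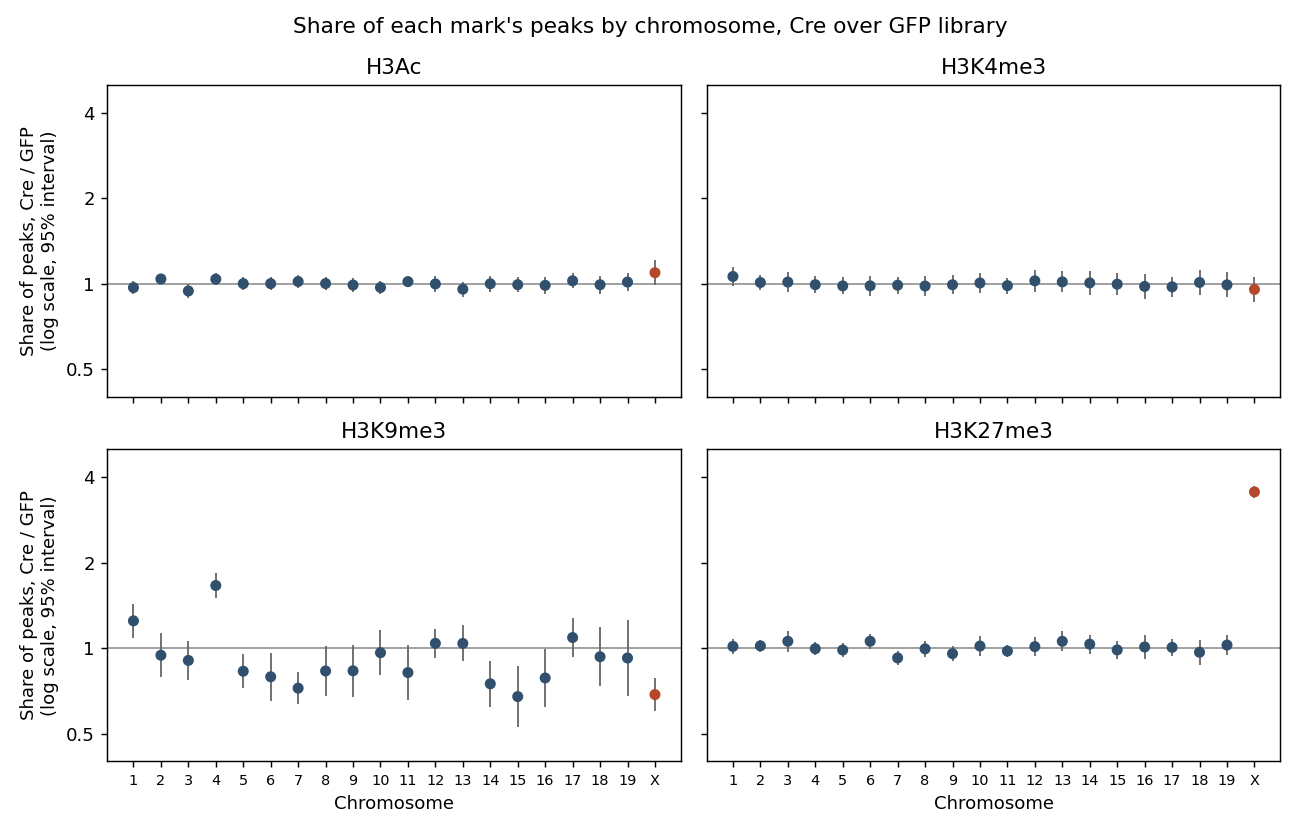
Points give the Cre to GFP ratio of the share of peaks on each chromosome, on a log axis with 95% intervals, for 4 marks. Autosome shares were taken without chromosome X, and the X share over all peaks. The X point stands at 3.54 for H3K27me3, and at 1.09 for H3Ac and 0.955 for H3K4me3.

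The highest-scoring GFP-only H3K27me3 peaks were autosomal. They lay on chromosome 18 from 61187022 to 61193324, with a score of 947.3, on chromosome 11 from 108843240 to 108848856, with 862, and on chromosome 17 from 34314521 to 34319108, with 715.2. The widest H3K27me3 domain lay at the same place in both libraries, on chromosome 11 from 96023454 to 96055635 in GFP cells and from 96023404 to 96060093 in Cre cells. Peaks of at least 10 kb numbered 257 in the GFP and 300 in the Cre list.

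H3K4me3 peaks that overlapped H3K27me3, as in the arrangement known as bivalent chromatin, made up similar shares in both libraries over all chromosomes. An overlap of peaks from bulk cells does not show both marks in the same cell. In the GFP library 12.3% of H3K4me3 peaks (11.9 to 12.7) overlapped H3K27me3, and in the Cre library 13.1% (12.7 to 13.6), where shifted positions gave 4.47% and 4.41%. On chromosome X the shares differed, 11.7% in the GFP and 25.3% in the Cre library. With at least 50% of the peak overlapping, they were 9.22% and 14.0%. No chance level was computed for chromosome X, where H3K27me3 peaks covered 2.53 Mb in GFP and 11.3 Mb in Cre cells. How much of the difference comes from that coverage was therefore not tested. Of the 18736 regions outside chromosome X with H3K4me3 in both libraries, 1824 carried H3K27me3 in both, 316 in the Cre library only and 193 in the GFP library only. H3Ac overlapped 80.1% of the GFP and 85.0% of the Cre H3K4me3 peaks. H3K27me3 and H3K9me3 were largely apart. H3K9me3 overlapped 0.727% of the H3K27me3 peaks in the GFP library and 0.231% in the Cre library, below the lowest value of 100 shifts in each, 0.904% and 0.258%.

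The last comparison was of heterochromatin. The Cre library held 3985 H3K9me3 peaks and the GFP library 10885, a ratio of 0.366 (0.353 to 0.380), and they covered 5.46 Mb and 15.8 Mb. Of the GFP peaks 18.99% (18.3 to 19.7) overlapped a Cre peak, and of the Cre peaks 60.1% (58.6 to 61.6) overlapped a GFP peak. The sharing was lower than for the other marks also when both lists were limited to equal numbers of top-scoring peaks, 35.7% of GFP and 44.9% of Cre peaks. The highest-scoring GFP-only H3K9me3 peak lay on chromosome X from 3194190 to 3199828, with a score of 1398. The next 2 lay close together on chromosome 7, from 9182594 to 9189916 and from 9172662 to 9180556, with scores of 1037 and 686.2.

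Chromosome 4 was the autosome with the highest Cre to GFP ratio of the share of H3K9me3 peaks, 1.66. Between 145 and 146 Mb the Cre list held 151 peaks and the GFP list 156, and between 146 and 147 Mb it held 171 and 130. All of the 5 highest-scoring Cre-only H3K9me3 peaks lay in these 2 windows, the first spanning 22933 bases from 145723235 to 145746167 with a score of 913.7. The widest GFP H3K9me3 peak, of 34051 bases from 146527414 to 146561464, lay there too, and Cre peaks covered 97.8% of it. H3K9me3 was sparser in the Cre library on chromosome 5 from 95 to 96 Mb, with 12 peaks against 115.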

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

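The tests of depth and of chromosome Y for the X chromosome pattern, the chromosome 4 windows, the allowance for dependence between H3K9me3 peaks and the comparison with weak neighbours were chosen after the results were seen. The test of X ranks, the test over all H3K9me3 windows, the test of neighbouring H3K4me3 peaks and the number of doubly marked regions expected from scores were set down before their results.

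The Cre to GFP ratio of the share of peaks on chromosome X was 3.54 for H3K27me3 and 0.687 for H3K9me3. The directions were opposite, but with 1 library per mark and condition the difference was not tested, and the H3K9me3 value lay within the range of the autosomes for that mark, 0.676 to 1.66. With equal numbers of top-scoring peaks it was 0.681, below the lowest autosome at 0.752. Peaks on chromosome Y were a signal that the comparisons did not use: 4 H3K4me3 peaks in the GFP and 5 in the Cre library, 4 and 3 H3Ac peaks, and 9 and 2 H3K9me3 peaks.

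The larger number of H3K27me3 peaks on chromosome X in Cre cells is unlike a difference in depth or threshold, which would move the autosomes the same way. The Cre list held more peaks than the GFP list on X, 7029 against 1967, and fewer outside it, 29352 against 34092. The ratio of the X share was 3.54, and 4.41 at a score of at least 100. Autosome ratios lay between 0.924 and 1.06, and 0.939 and 1.10. They are shares taken without X, so that they show only that the autosomes moved alike. Extra copies of an active chromosome X are not excluded. Among regions marked in both libraries, the median rank of chromosome X regions moved by 1.23 percentile points for H3Ac, level with the highest autosome. For H3K4me3 it moved by -2.35, within the autosome range of -3.61 to -1.73. The upper scores are saturated. With all peaks, the X share ratio was above every autosome for H3Ac, 1.09 against at most 1.04. For H3K4me3 it was below every autosome, 0.955 against at least 0.976. A larger share of cells with an inactive X, as in a culture with more female embryos, may account for the larger number of H3K27me3 peaks. All 7 chromosome Y regions with H3K4me3 or H3Ac in both libraries ranked lower in Cre than in GFP cells, where between 1.66% and 17.2% of regions of similar GFP rank moved down as far, but the 7 lie at only 4 positions, since 3 positions carry both marks. The sex of the embryos is not in the labels, and whether GFP and Cre cells came from the same embryos was unknown here. An effect of Rb deletion on the X chromosome was not tested and stays open, since each mark has 1 library per condition.

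The shorter H3K9me3 list in Cre cells may reflect lower depth or weaker enrichment: given the GFP scores, 1 of 50 windows of 1 Mb, on chromosome 5 from 95 to 96 Mb, passed the bound set beforehand, which would exclude them, with 7 peaks kept against 20.1 expected. That bound took peaks as independent, and it was set aside after the value was seen, because the variance over all windows was 5.14 times that of independent peaks after score and width were taken into account. The 2 windows between 145 and 147 Mb of chromosome 4 and the window from 85 to 86 Mb of chromosome 1 kept more peaks than expected, by 2.74, 2.55 and 2.09 SDs with that variance, and by 4.04, 3.76 and 3.07 SDs with the variance of the windows inside the range alone. The choice of variance moves them across the limit of 3 SDs, so that this count of kept peaks cannot tell depth alone from an uneven loss. It leaves out Cre-only peaks. In these windows, in the same order, the Cre list held 151, 171 and 59 peaks and the GFP list 156, 130 and 41. Cre peaks covered fewer bases in each, 358.3, 385.0 and 129.5 kb against 475.3, 509.6 and 173.9 kb. A difference in DNA copies would move both marks the same way; relative to the genome, H3K9me3 and H3K4me3 moved in opposite directions in 6 of the 6 windows outside the range with at least 3 GFP H3K4me3 peaks and any in Cre, but H3K4me3 was below the genome ratio also in 17 of the 25 such windows inside it, so that this decides nothing, and Rb deletion was not tested.

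The excess of regions with H3K4me3 and H3Ac in Cre cells only may come from a difference in depth or threshold. From the score deciles alone, with the marks lost independently, 240 such regions were expected in Cre and 30.4 in GFP cells, and the Cre to GFP ratio of observed over expected was 0.703 (0.548 to 0.913). The chances came from the same lists, so a real gain of marks would enter them too and is not excluded; 15 Cre-only regions against 1 GFP-only region held peaks in the upper 50% of both lists. A changed DNA copy number or strain segment would affect neighbouring peaks, and 11.2% (9.68 to 12.9) of the 1543 other Cre H3K4me3 peaks within 100 kb were Cre-only, against 11.0% over all other Cre H3K4me3 peaks (45.5% against 42.7% among those scoring up to 173.8). The control library, whose replicate number differs for GFP, the response to each virus and the loss of Rb were not tested and stay open.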

How the results depend on the processing

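Leaving out chromosome X, equal numbers and merging for the X shares, every setting of the doubly marked regions, and the score and equal-number settings of H3K4me3 peaks with H3K27me3 were chosen after the data were seen. Of 86 recomputed values, 38 stayed within the counting interval of the main value or within 1.5 times of a count, 46 moved beyond it and 2 turned direction from a value whose interval excluded 1; the cause was not tested. Those intervals are narrow. For covered lengths the interval was that of the peak ratio, scaled to the length ratio, and not a counting interval of bases. No paired analysis was possible because each mark has 1 library per condition. The planned settings for promoters, bivalent promoters and gene lists were not run. Depth is unknown, so that it limits each comparison of list lengths.

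The 2 that turned were the H3K4me3 peak ratio at a score of at least 100 and the H3K27me3 covered length without chromosome X (0.924, against 1.06). The first of them was 1.01 (0.985 to 1.03), an interval that included 1. The H3K27me3 peak ratio, 1.01 with an interval that included 1, was 1.04 at a score of at least 100 and fell on the other side of 1 after merging (0.992) and without X (0.861). H3K4me3 peaks after merging gave 0.983. At a score of at least 100, covered length ratios were 1.11 for H3K4me3, 1.07 for H3K27me3 and 0.316 for H3K9me3, the H3K9me3 peak ratio was 0.295, and the X share ratios were 4.41 for H3K27me3 and 0.474 for H3K9me3. Merged H3K27me3 peaks gave an X share ratio of 3.01.

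Percentages of GFP and of Cre peaks found in the other library at a score of at least 100 were 76.8 and 87.9 for H3Ac, 74.6 and 69.5 for H3K27me3, 94.2 for GFP H3K4me3 and 71.3 for Cre H3K9me3. With 50% of the peak overlapping they were 69.5 and 82.5 for H3Ac, 88.5 and 85.7 for H3K4me3, 11.8 and 55.2 for H3K9me3 and 61.8 and 58.3 for H3K27me3. With equal numbers of top-scoring peaks they were 79.3 and 80.7 for H3Ac, 91.7 and 85.6 for H3K4me3, and 35.7 and 44.9 for H3K9me3. Without chromosome X, H3K27me3 gave 68.3 and 77.3, so that the order of the 2 libraries turned.

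H3K4me3 peaks with H3K27me3 made up 9.59% of GFP and 9.75% of Cre peaks with 50% overlap, 8.51% and 9.86% at a score of at least 100, and 11.8% of GFP peaks with equal numbers. With 50% overlap, H3Ac lay at 79.4% and 83.5% of H3K4me3 peaks, and H3K9me3 at 0.311% and 0.0660% of H3K27me3 peaks. Regions with H3K4me3 and H3Ac in the Cre library only numbered 116, against 13 for GFP, with a score of at least 100 and no peak in the other library; GFP-only ones numbered 39 at a score of at least 100 in both libraries and 41 with equal numbers.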

Other observations

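H3K4me3 and H3K9me3, marks of opposite chromatin states, overlapped more often than shifted positions did. H3K9me3 overlapped 4.65% of the GFP H3K4me3 peaks (4.39 to 4.92) and 2.45% of the Cre ones (2.25 to 2.66), where shifts gave 1.13% and 0.439%. Many of these H3K4me3 peaks had no counterpart in the other library. In the GFP library 657 of the 1107 were GFP-only, against 2559 of all 23808 H3K4me3 peaks. In the Cre library 157 of the 554 were Cre-only, against 2859 of all 22621. The widest H3K4me3 peaks included such regions. The peak on chromosome 4 from 145410329 to 145426626 spanned 16298 bases in the GFP library and overlapped H3K9me3 in both libraries, with no H3Ac. On chromosome 7 a Cre peak of 17857 bases from 13418979 to 13436835 overlapped both H3K9me3 and H3Ac in both libraries. Between 145 and 146 Mb of chromosome 4, H3K4me3 peaks covered 92.1 kb in the Cre and 141.5 kb in the GFP library, while the H3K9me3 peaks covered 358.3 kb and 475.3 kb.

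Of the 411 Cre-only H3K4me3 peaks with Cre-only H3Ac, 87 overlapped H3K27me3 in the GFP library and 72 in the Cre library. Among all 2859 Cre-only H3K4me3 peaks, 660 and 680 did, so that the shares were not higher in the doubly marked regions. On chromosome 17 from 57365195 to 57367874 an H3K27me3 peak with a score of 402.6 was present in the GFP library only, and the H3K4me3 score in the Cre list was 1218.

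A hypothesis set down before its test was that the Cre-only regions with H3K4me3 and H3Ac lie near each other, as genes of local families gaining marks together would. After joining peaks within 5 kb, 59 of 400 regions lay within 200 kb of another one. Random sets of the same size, drawn as planned from all 2696 Cre-only H3K4me3 regions, gave a median of 45 (29 to 62 in the central 95%), and the observed number stood at percentile 94.8 of 10000 sets. Drawn only from the 1417 such regions with H3Ac in the Cre library, a change to the planned pool, the sets gave a median of 54 (37 to 73) and a percentile of 68.1. Closer spacing than in such sets was not detected.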
